A study of Homo sapiens with 96 samples.

How the data were processed

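RNA from K562 cells was measured in 96 libraries of 5 deposited tables, with 3 libraries in each of 32 groups. Per the labels' protocols, total RNA was isolated with RNeasy kits, libraries were made with KAPA RNA HyperPrep kits with removal of ribosomal RNA, and sequencing was done on a NextSeq500. The labels name Strand Avadis NGS 3.0 for single-end reads, 2-pass STAR for paired-end reads, the hg38 genome and DESeq2 with an adjusted p of 0.05 and an absolute log2 fold change of 0.585. For the J2_7 table the labels name Smart-3SEQ as an alternative library protocol and Trim Galore 0.6.7. The counting program, the strand setting, the annotation release, the doses, and the times of treatment in the construct, inhibitor and J2_7 tables are not given in the sources used here. The labels do not spell out EV, LF, SF, dLRRS or dCxxC. For the J2_7 table they name a double knockout of JARID2 and AEBP2 and wild-type cells, but do not say that J2_7 is the knockout.

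The authors deposited the BCOR, KDM2B, construct and inhibitor tables as raw counts (count per gene ID). The J2_7 table that the authors deposited holds estimated counts (expected count per gene symbol), of which 57.9% of the nonzero values are whole numbers, and these were rounded. The ID tables hold 60605 gene IDs, of which 60463 have a symbol, and 1195 share a symbol with a larger entry and kept their own ID. The J2_7 table holds 50037 symbols, 28456 of them current, after 92 spike-in entries were left out. Its 5961 entries whose symbol repeats another with a number added hold 4.44% of the counts and were kept. Columns of the KDM2B, construct and inhibitor tables were assigned to groups by name, and their replicate numbers are the column order, while those of the BCOR and J2_7 tables come from the labels.

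Each table was analysed on its own, since each table has its own control libraries. Median library totals were 14.38 (BCOR), 13.33 (KDM2B), 15.02 (construct), 10.04 (inhibitor) and 9.14 M counts (J2_7). Genes passed edgeR's filterByExpr, which left 14110, 14524, 15910, 13374 and 14649 genes in that order. Counts were normalized by TMM (factors 0.937 to 1.07) and fitted with edgeR's quasi-likelihood model with robust dispersion over all groups of a table, with common biological coefficients of variation of 0.083, 0.086, 0.059, 0.094 and 0.081. Every adjusted p of a gene comes from the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called with an adjusted p under 0.05 and an absolute log2 fold change above 0.585. The 35 comparisons were each time point against untreated, ligand against DMSO in each line and the differences of these effects from EV, each line against EV with DMSO, each treatment of the inhibitor table against DMSO with the interaction, each treatment against DMSO in mAID and in J2_7 cells, J2_7 against mAID with DMSO, and the differences of the effects between J2_7 and mAID.

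The test, the thresholds, the comparisons, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule named, in each of 10 leading comparisons, up to 12 rising and 8 falling genes with the largest fold change among called genes. These needed a mean of at least 2 CPM, no overlap between the libraries of the groups, and a symbol not dropped as a clone, locus or pseudogene name. In every other comparison the rule named up to 3 and 3. It also named the members of the gene lists and BCOR, KDM2B, JARID2, AEBP2 and EZH2 in every group. The no-overlap condition was not applied to differences of effects or to the interaction. Symbols that end in P and digits were dropped as pseudogene names, which also drops protein-coding genes with such symbols. Pseudogenes whose symbol ends in P alone were not dropped. Folds of genes with 0 counts in a group use a floor of 3 counts over the 3 libraries of that group and are lower bounds, and folds of genes with 1 to 3 counts are given with a 0.95 counting interval. Positions are those of GENCODE release 44 on hg38.

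The 23 gene lists were PRC1.1 subunits, PRC2 subunits, canonical PRC1 subunits, other variant PRC1 subunits, HOX genes, developmental transcription factors, erythroid, megakaryocyte, myeloid, stem and progenitor, cell cycle, cell-cycle inhibitor, MHC and antigen presentation, interferon response, aryl hydrocarbon receptor target, integrated stress response, heat shock, germline, growth factor and adhesion, lymphoid marker, fibroblast and epithelial marker, mitochondrially encoded and replication-dependent histone genes. Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over all lists and comparisons of a table. The genes called at 72 h in the KDM2B table were tested the same way in the construct, inhibitor and J2_7 tables. Of 652 list results in comparisons of 2 groups, 108 held members at 0 to 3 counts in a group, and setting these to their bound moved 27 medians by 0.01 or more and changed the sign of 5, all of them in lists whose test was not passed. Libraries without any effect were simulated 10 times from the fitted model to give the overlap and covariance that shared controls produce.

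Alternatives were DESeq2's size factors, no filter on low counts, DESeq2 in place of edgeR, a fit on only the groups of a comparison, each library left out in turn, a replicate block in the BCOR and J2_7 tables, the estimated correlation, and the response list taken at 24 h. Alternatives chosen after seeing the data were leaving out libraries under 0.5 of their table's median total, the J2_7 table without repeated entries, and the inhibitor table without processed pseudogenes and copies. A partner of a gene was a transcript that aligned with minimap2 over at least a share of 0.5 of its length, at 90% identity or more, and with at least 5 times its CPM. Intervals of medians come from 2000 resamples of genes. Other splits of the samples were all 10 splits of the 6 libraries of a pair of groups, or 60 splits for interactions. Neighbouring genes were those within 20 kb.

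The chain of normalization, fit and test was run on counts simulated from the fitted model, with 50 genes planted at each fold. It started from genes that had passed the filter, and no outlying library was simulated. At 2, 3 and 4-fold rises it called 88, 92 and 100% in the BCOR 72 h comparison, 80, 96 and 98% in the KDM2B 72 h comparison, 80, 90 and 100% for ligand in EV cells, 64, 82 and 86% for the difference of LF from EV, 74, 98 and 100% for GSK343 in the inhibitor table, and 82, 90 and 100% for ligand in mAID cells. Falls to 0.5-fold were called in 80, 70, 78, 60, 70 and 86% in the same order, and 2 to 5 unchanged genes were called per comparison. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and minimap2 2.31-r1302. Sequence reads were not analysed here. Results for a few genes are not reported.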

Results

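RNA was sequenced from K562 cells, a line from a chronic myeloid leukaemia with erythroid and myeloid features, in 96 libraries that make up 5 tables with 3 libraries in each of 32 groups. Cells of the BCOR and KDM2B tables carry a degron tag on the named subunit of PRC1.1, a Polycomb complex that ubiquitinates histone H2A, and were left untreated or given the ligand 5PhIAA for 2, 8, 24 or 72 h. The construct table crosses 5 cell lines, named EV, LF, SF, dLRRS and dCxxC, with DMSO or ligand. Cells of the inhibitor table received DMSO, ligand, the EZH2 inhibitor GSK343 or both, and those of the J2_7 table the same 4 treatments in KDM2B-mAID cells, called mAID here, and KDM2B-mAID_J2_7 cells, called J2_7, which both carry the KDM2B degron by their names. Library totals ran from 5806624 to 18519442 counts in the BCOR table, 10429112 to 19910440 in the KDM2B table and 2346542 to 22611557 in the construct table. They ran from 4268383 to 24545679 in the inhibitor table and 782663 to 12740071 in the J2_7 table. Fold changes come from edgeR with n = 3 libraries per group, and errors are standard errors (SE) on the log2 scale unless given as ± SD of CPM, counts scaled to library size. Each SE was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. Counting intervals and floors cover counting error only.

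The RNA of the degraded subunits was read first in every line, although RNA does not check the loss of a protein. Below, BCOR loss and KDM2B loss name treatment with the ligand in cells with that degron, where the protein was not measured here. Neither time course had a vehicle or untagged group. BCOR RNA rose in BCOR-degron cells from 307 ± 40.4 CPM to 627 at 8 h, 767 ± 13.1 at 24 h and 1075 ± 33.8 at 72 h (log2 fold change 1.81, SE 0.08, adjusted p = 3.8e-13). BCOR lies on chromosome X from 40049815 to 40177329. At 2 h it stood at 446 CPM (log2 fold change 0.54, adjusted p = 0.000319), under the fold threshold. In KDM2B-degron cells BCOR RNA rose from 254 ± 1.52 to 449 ± 15.3 CPM at 72 h (log2 fold change 0.82, SE 0.06, adjusted p = 1.01e-08). KDM2B RNA stood at 82.1 ± 2.36 CPM in EV cells with DMSO and was higher in the other construct lines. It stood at 2386 ± 146 in LF, 898 in SF, 2929 ± 166 in dLRRS and 3622 ± 60.6 in dCxxC cells (log2 fold changes 4.86, 3.45, 5.16 and 5.46). AEBP2 RNA, which encodes an accessory subunit of PRC2, was at 1.68 ± 0.395 CPM in J2_7 cells against 17.1 ± 1.80 in mAID cells (log2 fold change -3.34, SE 0.18, adjusted p = 1.13e-15). JARID2 RNA was at 90.1 ± 9.13 against 115 ± 12.7 CPM (-0.36, adjusted p = 0.00137, under the fold threshold), and gene counts do not show whether a transcript was edited. KDM2B RNA was lower in J2_7 than in mAID cells with DMSO (1.65 ± 0.799 against 3.09 ± 0.960 CPM, log2 fold change -0.93, SE 0.30, adjusted p = 0.0174), a call that ended without mAID DMSO library 1 or J2_7 DMSO library 3.

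**Figure D1:**
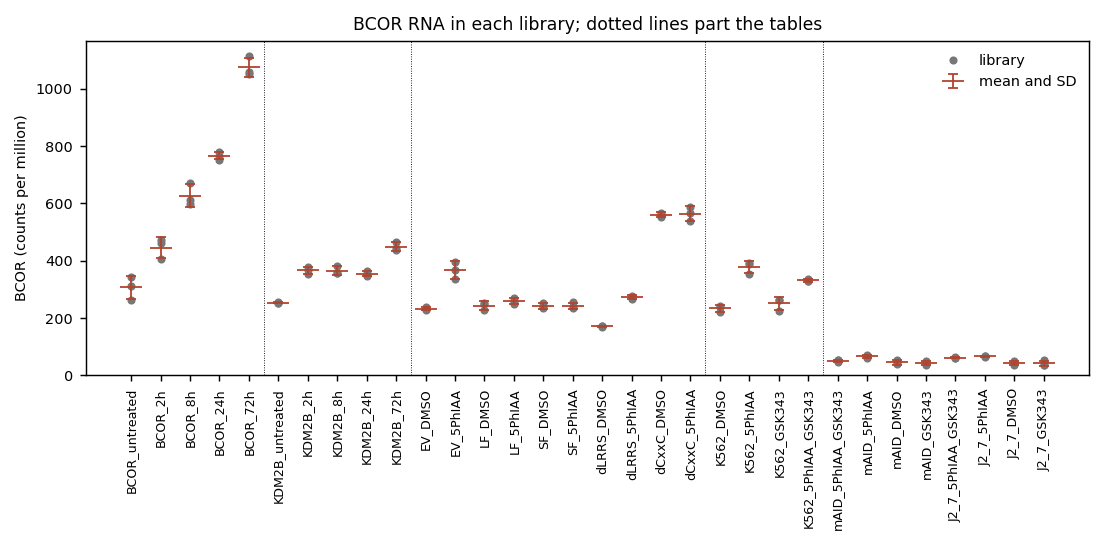
BCOR RNA in CPM (vertical axis) in each library of every group (horizontal axis). Dots are libraries, bars and whiskers give the mean and SD of the 3 libraries of a group, and dotted lines part the tables.

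The BCOR time course asked which genes respond as BCOR is degraded. Genes were ranked among called genes with a mean of at least 2 CPM, no overlap between libraries and a symbol kept by the naming rule. Among these, the largest rises at 72 h were those of SRRM3, a neuronal splicing regulator (18.5-fold, from 0.243 ± 0.104 to 4.67 ± 0.441 CPM; log2 fold change 4.21, SE 0.34, adjusted p = 8.37e-09), and of the potassium-chloride cotransporter gene SLC12A7 (16.9-fold, from 1.81 ± 0.547 to 30.4 ± 1.25 CPM, adjusted p = 4.19e-11). SRRM3 lies on chromosome 7 from 76201896 to 76287288 and SLC12A7 on chromosome 5 from 1050384 to 1112063. ZBTB16, which encodes a zinc-finger transcription factor of blood progenitors, rose 12.4-fold (log2 fold change 3.63, SE 0.21, adjusted p = 2.57e-11), and the receptor tyrosine kinase gene FGFR1 rose 8.55-fold (3.10, SE 0.15, adjusted p = 7.63e-13). ZBTB16 lies on chromosome 11 from 114059041 to 114256765 and FGFR1 on chromosome 8 from 38400215 to 38468834. NR2F1 (3.72), SMARCD3 (3.65), S100A10 (3.59), FAM167A (3.33) and PDGFA (3.22, adjusted p = 0.000904) rose as well, with CMTM7, TUBB2B and LAMC1 at 2.91 to 2.95. TRANK1, on chromosome 3 from 36826819 to 36945057, fell from 59.0 to 8.44 CPM (log2 fold change -2.82, SE 0.56, adjusted p = 0.00589). So did MME (-2.40), DES (-2.11, adjusted p = 1.7e-06), the cathepsin S gene CTSS (-2.04) and RNASE1 (-1.99). Counts of called genes grew from 118 at 2 h (88 higher, 30 lower) to 382 at 8 h (345, 37), 592 at 24 h (428, 164) and 1004 at 72 h (669, 335), with 74 without library 3 of 2 h and 391 without library 2 of 24 h. At 2 h FOSL2 rose (from 4.52 to 16.1 CPM, log2 fold change 1.81, adjusted p = 2.63e-06), FHDC1 (from 5.63 to 19.6 CPM, 1.81, adjusted p = 4.52e-08) and the Notch ligand gene JAG1 (1.64, adjusted p = 2.53e-05). Of the genes called higher at 24 h, 340 were also higher at 72 h against 20.3 if the lists were independent, and 95 were lower at both (3.9 if independent). Simulated libraries that shared their controls gave at most 0.1. They held no effect, so hardly any gene is called in them, and this count cannot measure what shared controls add to the overlap. The covariance of the 24 h and 72 h log2 fold changes was 0.153 over genes, 0.0277 in the simulations, a difference of 0.125. Genes are not independent replicates in this covariance or in any correlation over genes.

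Among gene lists at 72 h of BCOR loss, growth factor and adhesion signalling genes rose (11 of 27 higher and 1 lower, the same counts adjusted over the list alone; median log2 fold change 0.48, adjusted p = 4.06e-10). They included PDGFB (2.16), EFNB2 (1.48) and JAG1 (1.27) beside FGFR1 and PDGFA. Developmental transcription factors rose too (9 of 35, 12 adjusted over the list alone; median 0.48, adjusted p = 5.9e-09). Among them were EMX1 (2.28), DLX4 (1.99) and TFAP2A (1.93). Outside the lists that changed, the cell-cycle inhibitor gene CDKN1A rose (1.70, SE 0.33, from 15.6 to 50.3 CPM), as did the myeloid factor gene CEBPA (2.69) and the antigen transporter gene TAP1 (1.67). Of the erythroid list 6 of 31 genes fell (6 adjusted over the list alone; median -0.20, adjusted p = 0.0215; adjusted p = 0.664 with an estimated correlation). AHSP, whose product stabilises alpha globin, fell most (-1.97, SE 0.17, adjusted p = 1.96e-07), with CA1 at -1.35 and KLF1 at -0.71. The megakaryocyte list had 4 of 10 genes higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0637), including ITGB3 (1.15). The myeloid list had 3 of 13 higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.973). Among PRC2 subunit genes 1 of 13 was lower, EED (-0.71, adjusted p = 1.53e-06; 1 adjusted over the list alone, list adjusted p = 0.34). Among aryl hydrocarbon receptor targets 1 of 4 was lower, NQO1 (-0.70, 1 adjusted over the list alone, list adjusted p = 0.293). Replication-dependent histone genes, a list included as a sign of library type, were lower at 24 h (14 of 16, 14 adjusted over the list alone; median -0.70, adjusted p = 1.11e-33) and at 72 h (16 of 16, 16 adjusted over the list alone; median -0.91, adjusted p = 1.39e-38).

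The KDM2B time course was read at 72 h among called genes with a mean of at least 2 CPM, no overlap between libraries and a kept symbol. Among these, SRRM3 rose most (from 0.109 ± 0.095 to 4.71 ± 0.852 CPM, log2 fold change 5.37, SE 0.41, adjusted p = 1.77e-08). AIF1L, whose product binds actin, rose 10.4-fold (from 1.71 ± 0.23 to 17.8 ± 2.39 CPM, 3.38, SE 0.17, adjusted p = 3.66e-11), and the CaMKII inhibitor gene CAMK2N1 rose 9.78-fold (3.29, SE 0.20, adjusted p = 9.72e-10). AIF1L lies on chromosome 9 from 131096476 to 131123152 and CAMK2N1 on chromosome 1 from 20482391 to 20486210. CHAC1, which degrades glutathione in stressed cells, rose by 3.36 (SE 0.25, adjusted p = 4.75e-07) and the mTORC1 inhibitor gene DDIT4 by 3.01 (from 94.4 to 761 CPM). CHAC1 lies on chromosome 15 from 40952962 to 40956512 and DDIT4 on chromosome 10 from 72273919 to 72276036. DNAJC22, C1QL4, CARMIL2, NXPH4, MARCKS, PITPNC1 and ASS1 rose by 2.92 to 3.59. IL1RL1, the receptor gene for interleukin-33, fell (log2 fold change -2.61, SE 0.42, adjusted p = 0.00013), as did CD24 (-1.38, SE 0.14, adjusted p = 1.22e-06) and CCDC80 (-1.75). IL1RL1 lies on chromosome 2 from 102311502 to 102352037 and CD24 on chromosome 6 from 106969831 to 106975627. Called genes numbered 255 at 2 h (184 higher, 71 lower), 616 at 8 h (535, 81), 1817 at 24 h (1385, 432) and 1526 at 72 h (951, 575), with 403 at 8 h without its library 2. FHDC1 led at 2 h (from 1.73 to 9.33 CPM, 2.43, adjusted p = 5.81e-08). The immediate-early gene EGR1 fell (from 71.4 to 18.9 CPM, -1.93, adjusted p = 0.00333) and was low at 8 h (-2.06, adjusted p = 0.00166). Between 24 h and 72 h, 800 genes were higher at both (90.7 if independent) and 191 lower at both (17.1). The covariance was 0.246 against 0.0324 in simulations, a difference of 0.213.

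Integrated stress response genes stood out in the KDM2B time course, with 16 of 17 higher at 24 h (16 adjusted over the list alone; median log2 fold change 2.01, adjusted p = 3.46e-43) and 15 at 72 h (15 adjusted over the list alone; median 1.53, adjusted p = 4.5e-33). At 24 h CHAC1 rose 12.6-fold (3.65, SE 0.25, adjusted p = 2.02e-07), DDIT4 by 3.29 (from 94.4 to 924 CPM), VLDLR by 3.06, SESN2 by 2.40, ATF3 by 2.28 and the transcription factor gene ATF4 by 0.98. The same list rose far less with ligand in mAID cells, as given below. It was also clearly higher in LF than in EV cells with DMSO alone. The cause of its rise in the time course was not tested. Heat shock genes fell at 24 h (7 of 12, 7 adjusted over the list alone; median -0.79, adjusted p = 1.01e-09; adjusted p = 0.142 with an estimated correlation). HSPA1A fell by 1.78 (from 207 to 60.3 CPM) and HSPA1B by 1.57. At 72 h developmental transcription factors rose (13 of 34, 16 adjusted over the list alone; median 0.64, adjusted p = 1.29e-06), among them EMX1 (2.96). Growth factor and adhesion genes had 11 of 30 higher and 1 lower (the same adjusted over the list alone; median 0.51, adjusted p = 1.48e-06; adjusted p = 0.0608 with an estimated correlation). MHC and antigen presentation genes had 3 of 14 higher and 1 lower (the same adjusted over the list alone; median 0.47, adjusted p = 0.0383; adjusted p = 0.32 with an estimated correlation), with HLA-C at 1.89. CDKN1A rose (1.54, SE 0.10), the only one called of 5 inhibitor genes (1 adjusted over the list alone; list adjusted p = 0.011; adjusted p = 0.141 with an estimated correlation). The erythroid list had 1 of 31 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.536), with AHSP at -1.06.

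Over the 13700 genes tested in both time courses, 380 were higher at 72 h in both (633 after BCOR loss, 865 after KDM2B loss, 40 if independent) and 87 lower (327 and 500, 11.9 if independent). SRRM3, KLF12, NXN, ABCG2, COL6A1, FGFR1, FOXD1, GATA6, NR2F1 and CEBPA were among those higher in both. The rank correlation of the log2 fold changes was 0.376 at 72 h, 0.252 at 24 h, 0.373 at 8 h and 0.442 at 2 h, and the shared higher genes numbered 248, 192 and 48 at 24, 8 and 2 h (37.4, 12.2 and 1.1 if independent). At 72 h, 4 and 1 genes were called in opposite directions.

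**Figure D2:**
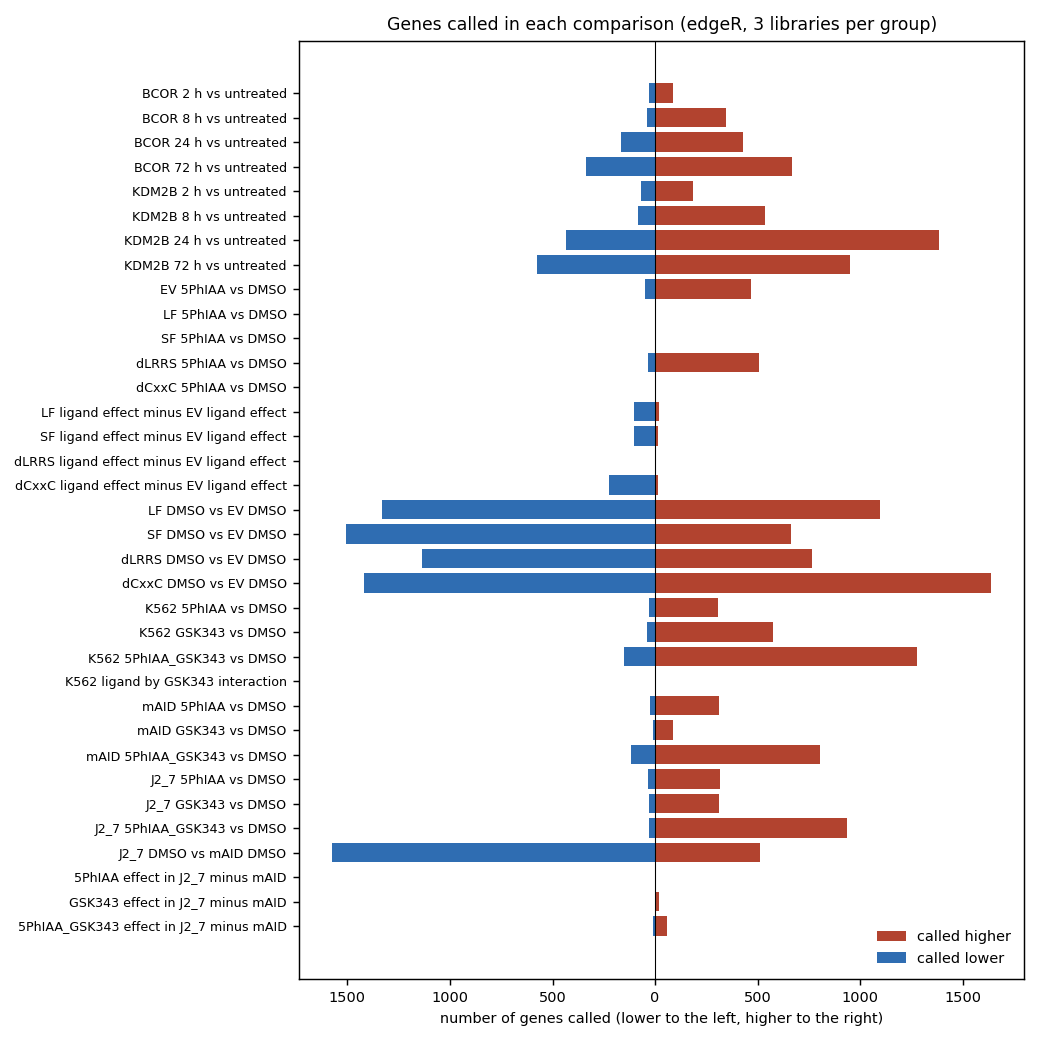
Number of genes called in each comparison (horizontal axis), higher to the right and lower to the left, with 3 libraries per group. Called genes passed an adjusted p of 0.05 and a log2 fold change of 0.585.

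In the construct table the question was whether the constructs, which all had more KDM2B RNA than EV, change the response to the ligand. EV cells called 520 genes (469 higher, 51 lower). AIF1L rose 4.67-fold (from 3.21 ± 0.255 to 13.9 ± 3.17 CPM; log2 fold change 2.22, SE 0.14, adjusted p = 1.3e-15), PDGFA by 1.74 (SE 0.12, adjusted p = 1.18e-13), the Notch receptor gene NOTCH2 by 1.79 (adjusted p = 4.03e-09), SLC12A7 by 1.79 and UBASH3B by 2.49. NOTCH2 lies on chromosome 1 from 119911553 to 120100779. AKR1C2 fell (-0.94, adjusted p = 1.09e-05) with the receptor chain gene IL2RG (-1.05). dLRRS cells called 542 (508 higher, 34 lower), with AIF1L at 2.27 (SE 0.12, adjusted p = 4.86e-18), EEF1A2 at 2.47 and PCDH1 at 2.80. LF cells called 1 gene, DDX46, which encodes an RNA helicase of splicing (0.69, SE 0.06, from 264 ± 25.6 to 426 ± 11.4 CPM, adjusted p = 2.18e-11). SF cells called 3 genes, DDX46 (0.69, adjusted p = 1.92e-11), the red-cell anion exchanger gene SLC4A1 (0.77, adjusted p = 7.83e-05) and INSR (1.497, adjusted p = 0.0251, named after its value was seen). DDX46 lies on chromosome 5 from 134758771 to 134855133 and SLC4A1 on chromosome 17 from 44248390 to 44268141. dCxxC cells called FTX (0.71, adjusted p = 0.0468), GPR89A (0.67, adjusted p = 0.0387) and MUC4 (0.59, adjusted p = 0.0387). Leaving out single libraries ended each of these 3 calls, and 0 genes were called without any 1 of the DMSO libraries or of ligand libraries 2 and 3. In LF cells 25 genes were called without ligand library 1, 2 without ligand library 2, and 2 and 5 without DMSO libraries 2 and 3, while 27 were called without a filter and 3 by DESeq2.

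The ligand effect itself differed from that of EV in 119 genes for LF (17 higher, 102 lower), 116 for SF (14, 102), 241 for dCxxC (14, 227) and 6 for dLRRS (4, 2). For dLRRS the count was 71 without EV ligand library 2, 2 without EV ligand library 3 or EV DMSO library 1, 3, 3 and 1 without dLRRS DMSO libraries 1, 2 and 3, and 11, 3 and 3 without its ligand libraries, and for SF it was 77 without EV DMSO library 1. AIF1L differed in LF (-1.87) and SF cells (-1.75), EMILIN2 in LF cells (-1.57), and GATA6 (-2.92) and NXPH4 (-2.65) in dCxxC cells. The 6 in dLRRS cells were PCDH1 (1.41), EEF1A2 (1.23), EGR1 (0.68) and, named after their values were seen, MDK (0.67), TP53INP1 (-0.86) and LINC02693 (-0.61). Of the 951 genes that rose at 72 h of KDM2B loss, 931 were tested here, and their median log2 fold change with ligand was 0.54 in EV cells (329 called higher, adjusted p = 5.08e-55) and 0.57 in dLRRS cells (338 called higher). Medians were 0.13 in LF cells (adjusted p = 3.65e-09; adjusted p = 0.00274 with an estimated correlation), 0.08 in SF cells (adjusted p = 0.00109; adjusted p = 0.0628 with an estimated correlation) and 0.04 in dCxxC cells (adjusted p = 0.0719). The median of each gene's difference from EV was -0.37 for LF (68 called lower), -0.40 for SF (67), -0.52 for dCxxC (176) and 0.02 for dLRRS (adjusted p = 0.592). With DMSO, their medians against EV were 0.76 in dCxxC (509 called higher), -0.13 in LF, -0.55 in SF and -0.38 in dLRRS cells. The weak ligand effect in dCxxC cells thus goes with genes that were already higher without ligand. The 569 genes of the falling list had medians of -0.10 in EV cells (16 lower, adjusted p = 2.83e-07) and -0.10 in dLRRS cells (adjusted p = 7.66e-06). Developmental transcription factors rose with the ligand in EV (11 of 42, 14 adjusted over the list alone; median 0.52, or 0.60 with genes at 0 to 3 counts at their bound, adjusted p = 8.92e-09), and growth factor and adhesion genes likewise (9 of 31, 9 higher and 1 lower adjusted over the list alone; median 0.32, adjusted p = 2.19e-09). EV ligand library 1 held 8.06% mitochondrial counts against 1.12 to 1.28% in the other libraries of its group. It was also the shallowest of the construct table (2.35 M counts, median 15.02 M). Its chi-square per gene against counting noise was 84.6 and 77.5 with libraries 2 and 3, and 2.99 between those. EV cells with ligand enter every difference from EV, and without shallow libraries these counts stayed within 1.5 times.

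**Figure D3:**
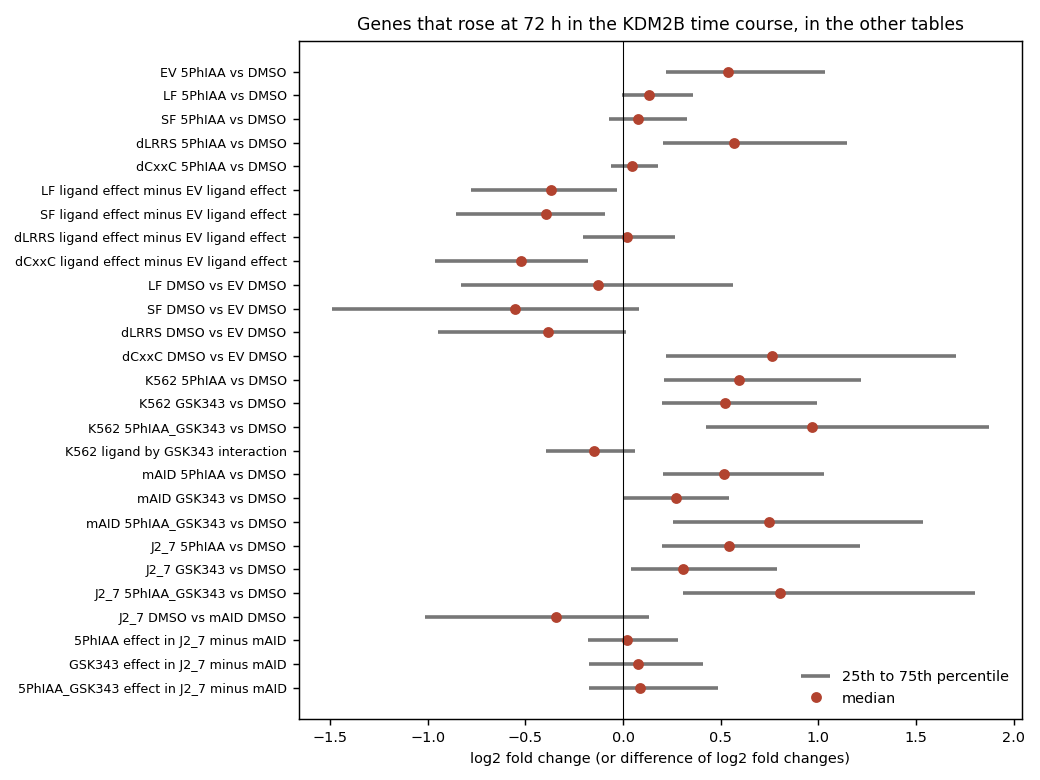
Log2 fold changes, or differences of log2 fold changes (horizontal axis), of the genes that rose at 72 h of KDM2B loss, in each comparison of the other tables (vertical axis). Points are medians over genes and bars run from the 25th to the 75th percentile.

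With DMSO alone the lines differed from EV in 2427 genes for LF (1097 higher, 1330 lower), 2171 for SF (664, 1507), 1901 for dLRRS (767, 1134) and 3060 for dCxxC (1640, 1420), and differences between lines that were grown apart are included. In dCxxC cells FGFR1 (from 0.109 to 13.4 CPM, adjusted p = 2.14e-20), TBX3 (4.72), the megakaryocytic factor gene FLI1 (4.80), JAG1 (3.75, SE 0.17) and PDGFA (3.38, SE 0.11) rose. LHX1 was 192-fold higher (counting interval 65.3 to 935) and ONECUT3 at least 291-fold higher. SLC4A1 (from 97.8 to 5.04 CPM, -4.27, SE 0.11, adjusted p = 1.64e-30), CA1 (-3.97, chromosome 8 from 85327608 to 85379014) and AHSP (-3.51) fell. SF cells had less PDGFA (-2.84), TBX1 (78.9-fold lower, counting interval 26.7 to 385), SEMA4D (-4.87) and the interferon-induced sensor gene IFIH1 (-3.85). In LF cells WWC3 (-4.40, SE 0.25) and OAS3 (-3.57) were lower and CHAC1 (3.66, SE 0.14, from 3.36 to 43.3 CPM) and INHBE (3.66) higher. dLRRS cells had less PCDH1 (-3.67) and ABCB1 (-3.55). The genes that rose at 72 h of KDM2B loss had a median of 0.76 in dCxxC (509 called higher, 36 lower), -0.55 in SF (87 higher, 373 lower) and -0.38 in dLRRS cells (53 higher, 267 lower). In LF cells their median was -0.13 with 200 higher and 216 lower, where the list test pointed up, so median and test differ in sign (adjusted p = 0.0463; adjusted p = 0.266 with an estimated correlation).

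Gene lists between the lines with DMSO set dCxxC apart from EV. Developmental transcription factors (32 of 42, 32 adjusted over the list alone; median 1.41, adjusted p = 3.96e-20) and HOX genes (9 of 18, 9 adjusted over the list alone; median 0.76, adjusted p = 0.00261) were higher in dCxxC cells. So were growth factor and adhesion genes (16 of 31 and 1 lower, the same adjusted over the list alone; median 0.68, adjusted p = 7.07e-13). MHC genes (7 of 13, 7 adjusted over the list alone, adjusted p = 0.00218) and myeloid genes (10 of 17, 10 adjusted over the list alone, adjusted p = 5.51e-05) were higher too, with HLA-C at 2.43 and the lysozyme gene LYZ at 2.59. Megakaryocyte genes had 10 of 15 higher and 1 lower (the same adjusted over the list alone; median 1.67, adjusted p = 1.35e-05; adjusted p = 0.0894 with an estimated correlation). The cell-cycle inhibitor list had 3 of 5 higher (3 adjusted over the list alone; adjusted p = 1.79e-05), with CDKN1A at 1.959. PRC1.1 subunit genes had 2 of 10 higher, KDM2B and BCOR (2 adjusted over the list alone, adjusted p = 2.47e-07). KDM2B, which was higher in every construct line than in EV, stood at 5.46 here. The test of a list that holds it is therefore no result about the other subunit genes. Lymphoid markers had 2 of 3 lower (2 adjusted over the list alone; adjusted p = 0.384). All 13 mitochondrially encoded genes were lower in dCxxC cells (13 adjusted over the list alone; median -1.60, adjusted p = 1.23e-08; adjusted p = 0.256 with an estimated correlation), a list included as a sign of RNA quality. Erythroid genes were lower in every other line than in EV, with 13 of 31 lower in LF (median -0.50, adjusted p = 4.07e-18) and 17 in SF cells (-0.59, adjusted p = 2.9e-23). In dLRRS cells 12 were lower and 1 higher (-0.49, adjusted p = 1.77e-08) and in dCxxC cells 19 were lower (-0.88, adjusted p = 2.53e-35), each count the same adjusted over the list alone. Their interferon response lists were lower in LF (10 of 21, 11 adjusted over the list alone; median -0.89, adjusted p = 0.000475) and SF cells (9, 9 adjusted over the list alone; -0.66, adjusted p = 3.61e-05). Integrated stress response genes were higher in LF cells (16 of 17, 16 adjusted over the list alone; median 1.80, adjusted p = 1.45e-57). In SF cells 8 were higher and 1 lower (the same adjusted over the list alone; median 0.71, adjusted p = 2.6e-12; adjusted p = 0.0597 with an estimated correlation). Stem and progenitor genes in SF cells had 3 of 13 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.0321; adjusted p = 0.109 with an estimated correlation), with MYB at 0.87 and KIT at 1.18. Canonical PRC1 subunit genes had 3 of 12 lower in LF cells (3 adjusted over the list alone, adjusted p = 0.144), CBX2, CBX6 and CBX7. Fibroblast and epithelial markers had 2 of 6 lower in dLRRS cells (2 adjusted over the list alone; adjusted p = 0.119), COL1A1 and KRT8.

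**Figure D4:**
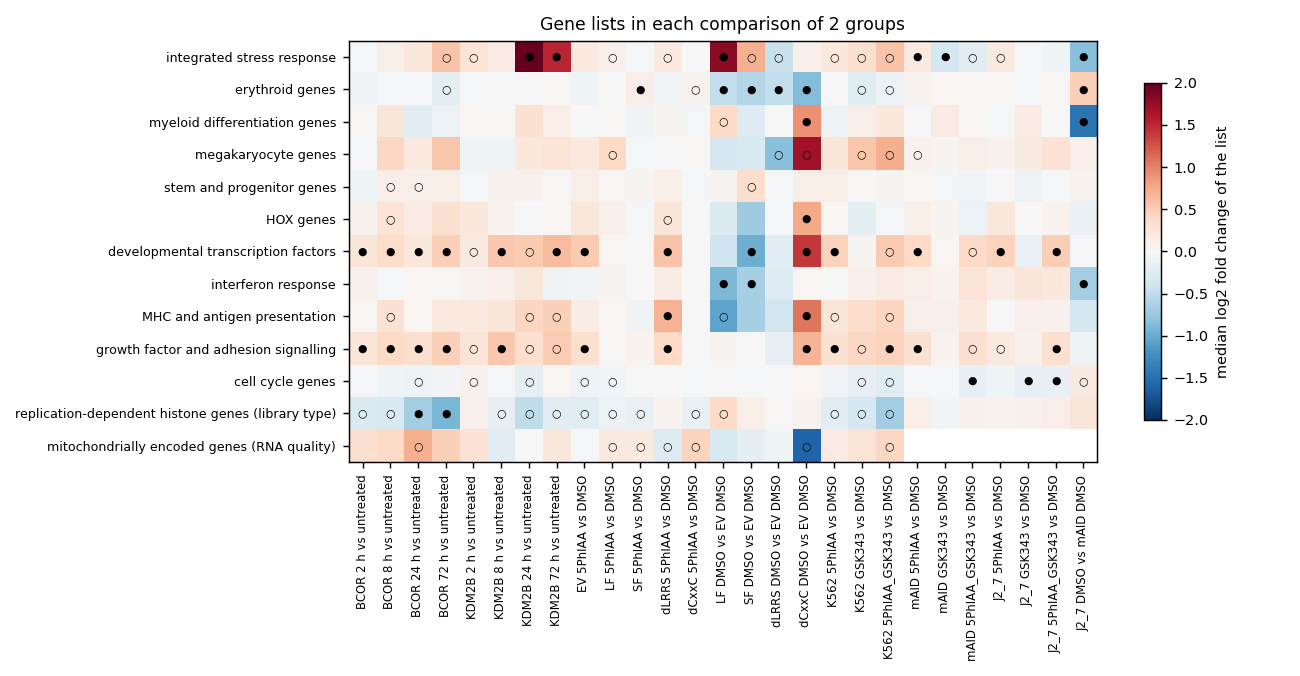
Median log2 fold change (colour) of 13 gene lists (vertical axis) in each comparison of 2 groups (horizontal axis). Filled circles mark lists with an adjusted p under 0.05 with preset and estimated correlation, open circles those with the preset correlation only, and white cells were not tested.

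The inhibitor table asked how loss of KDM2B and inhibition of EZH2, the enzyme of PRC2, combine. With ligand AIF1L rose 5.85-fold (from 3.72 ± 0.650 to 21.9 ± 1.73 CPM; log2 fold change 2.55, SE 0.14, adjusted p = 2.25e-08), SLC12A7 by 2.37 (SE 0.19, adjusted p = 1.76e-06), CAMK2N1 by 2.31, EMILIN2 by 2.45, PTPRU by 2.18, NOTCH2 by 1.94 and EEF1A2 by 1.90 (adjusted p = 5.78e-08). IL1RL1 (-1.20, SE 0.17, adjusted p = 0.000757), TNS4 (-1.70) and RNASE1 (-0.99) fell. GSK343 raised the tubulin gene TUBA1A (2.29, SE 0.16, from 9.16 to 45.7 CPM, adjusted p = 9.92e-08), TMEM158 (2.11, adjusted p = 9.92e-08), CAMK2N1 (2.37, adjusted p = 2.98e-05), NOTCH2 (2.21) and LIPG (2.21). TUBA1A lies on chromosome 12 from 49184686 to 49189080 and TMEM158 on chromosome 3 from 45224466 to 45226287. EIF2S3B, HSP90AB3P, CSNK2A3, HSP90AA2P and UQCRHL, which resemble copies of highly expressed genes, were also called higher with GSK343 (2.04 to 3.92) and their values are uncertain. With both, AIF1L rose 13.8-fold (3.79, SE 0.13, adjusted p = 1.71e-11), CAMK2N1 by 3.82 (from 0.868 to 12.4 CPM), FGFR1 by 4.21 (from 0.212 to 4.09 CPM), NOTCH2 by 3.64 and NECTIN1 by 4.43 (from 0.212 to 4.77 CPM). GOLM1 was 39.7-fold higher (counting interval 13.4 to 194). Ligand called 341 genes (309 higher, 32 lower; 211 without DMSO library 1 and 216 without DMSO library 3), GSK343 613 (574, 39) and both 1427 (1275, 152). Without processed pseudogenes and genes that resemble copies, alternatives chosen after the data were seen, GSK343 called 360. No gene passed the test of the interaction between ligand and GSK343 (0 called, 497 with an unadjusted p under 0.05, and 426 by DESeq2). The interaction of the 827 genes of the list that rose with KDM2B loss had a median of -0.15 (adjusted p = 3.44e-05). The same list had medians of 0.60 with ligand (230 called higher), 0.52 with GSK343 (184 higher, 1 lower) and 0.97 with both (504 higher, 1 lower). Ligand and GSK343 shared 149 higher genes (13.3 if independent) and 7 lower genes (0.1 if independent) against the same DMSO libraries. The covariance was 0.119, 0.0392 in simulations, a difference of 0.0796.

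Growth factor and adhesion genes rose with ligand in the inhibitor table (7 of 27, 9 adjusted over the list alone; median 0.30, adjusted p = 1.07e-07), with PDGFA at 1.80, EFNB2 at 1.82 and JAG1 at 1.44, and with both treatments (11 higher and 1 lower, the same adjusted over the list alone; adjusted p = 1.07e-07). Developmental transcription factors rose with ligand (2 of 29, 6 adjusted over the list alone; median 0.47, adjusted p = 2.61e-05). With both treatments 12 rose (13 adjusted over the list alone; median 0.52, adjusted p = 0.00464; adjusted p = 0.0869 with an estimated correlation). CDKN1A rose with ligand (1.41), with GSK343 (1.45) and with both (2.33, SE 0.18, adjusted p = 1.4e-07). The cell cycle list was lower with both (1 of 31 lower, MCM5, 1 adjusted over the list alone; median -0.24, adjusted p = 1.07e-07; adjusted p = 0.232 with an estimated correlation). Histone genes were lower with both (12 of 16, 12 adjusted over the list alone; median -0.70, adjusted p = 2.11e-17; adjusted p = 0.176 with an estimated correlation), with H4C3 at -1.21.

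**Figure D5:**
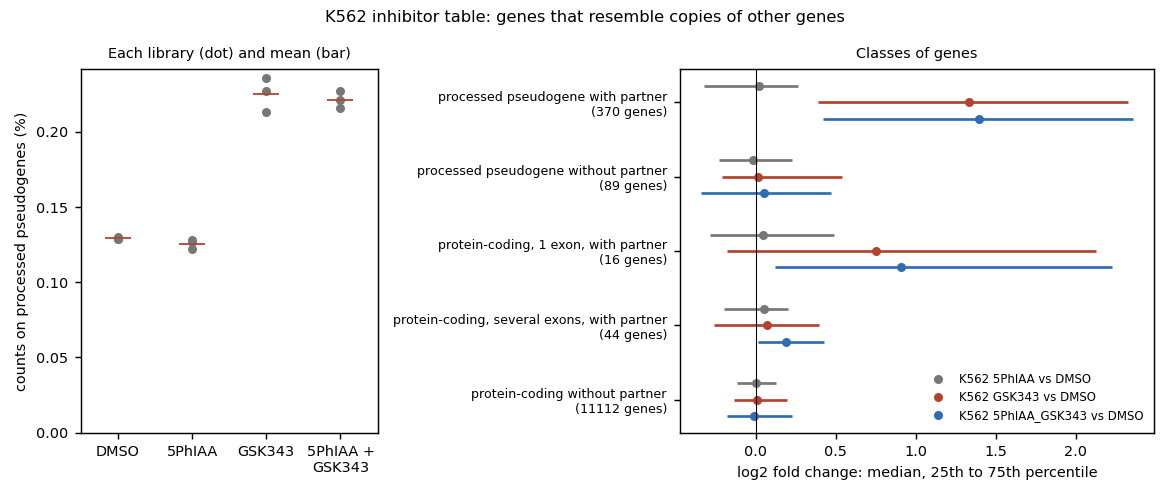
Left, share of counts on processed pseudogenes (vertical axis, percent) in each library of the inhibitor table (dots) and group means (bars). Right, median log2 fold change (points, horizontal axis) with 25th to 75th percentile (lines) of gene classes with or without an expressed partner of similar sequence.

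The J2_7 table asked whether the response to KDM2B loss differs between J2_7 and mAID cells. Its labels name a double knockout of JARID2 and AEBP2, accessory subunits of PRC2, and wild-type cells, without saying which group is which. In mAID cells the ligand raised AIF1L 5.90-fold (from 2.37 to 13.6 CPM; log2 fold change 2.56, SE 0.20, adjusted p = 4.11e-10), CAMK2N1 by 2.42 (SE 0.15, adjusted p = 4.29e-12), NXPH4 by 2.63, CARMIL2 by 2.20, the receptor gene ERBB3 by 2.07 and FOXO1 by 1.75. It lowered TNS4 (-0.94) and AKR1C1 (-0.68, adjusted p = 8.43e-07). In J2_7 cells CAMK2N1 (2.35, SE 0.15, adjusted p = 5.36e-12), CARMIL2 (2.40), AIF1L (2.16, adjusted p = 4.96e-08), MARCKS (1.94) and TMEM54 (1.79, adjusted p = 1.06e-11) rose and EGR1 fell (-0.83, adjusted p = 0.000162). Called genes with ligand numbered 338 in mAID (312 higher, 26 lower) and 350 in J2_7 cells (317, 33; 231 without its ligand library 1). The effect differed in 1 gene, LSR (0.77; 0 called without mAID ligand library 1 or 2 or J2_7 ligand library 3), while 488 had an unadjusted p under 0.05. Of the genes that rose with KDM2B loss in their own time course, 745 were tested. Their medians were 0.52 in mAID (207 called higher) and 0.54 in J2_7 cells (199 called higher), and the median of each gene's difference was 0.02 (adjusted p = 0.472). GSK343 called 97 genes in mAID (88 higher, 9 lower) and 339 in J2_7 cells (311, 28), and 18 differed, all higher in J2_7 cells. Those 97 were 55 and 63 without mAID DMSO libraries 1 and 3 and 63 and 60 without its GSK343 libraries 1 and 2, and those 18 were 8 and 10 without J2_7 GSK343 libraries 2 and 3. The sterol synthesis gene HMGCS1 rose in mAID (1.01, SE 0.10, from 112 to 227 CPM, adjusted p = 7.77e-08) and J2_7 cells (1.94, SE 0.10, adjusted p = 2.01e-14). It lies on chromosome 5 from 43287470 to 43313512. TMEM158 rose in both (1.103 and 1.75), and TUBA1A rose in mAID cells (1.13). The list medians with GSK343 were 0.27 and 0.31, and the median of each gene's difference was 0.08 (adjusted p = 0.0194). Both treatments called 923 (805 higher, 118 lower) and 966 (934, 32), with 64 that differed (56 higher, 8 lower) and list medians of 0.75 and 0.80. Those 64 were 39 and 214 without mAID libraries 1 and 3 with both, 27 and 33 without J2_7 libraries 2 and 3 with both, 33 without mAID DMSO library 1, and 29 and 24 without J2_7 DMSO libraries 2 and 3. SRRM3 was 75.6-fold higher in mAID (counting interval 20.4 to 632), and FOXD1 (from 0.188 to 6.35 CPM) and RTN4R (4.53, SE 0.23) rose in J2_7 cells. Ligand and GSK343 shared 40 higher genes in mAID (1.9 if independent) and 75 in J2_7 cells (6.7 if independent), with covariances of 0.0744 (0.0323 in simulations, a difference of 0.0421) and 0.104 (0.038, a difference of 0.0657).

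With DMSO, J2_7 cells differed from mAID cells in 2087 genes (513 higher, 1574 lower), with every other difference between the cell lines included. CDCA7L (from 0.731 to 14.4 CPM, log2 fold change 4.26, SE 0.21, adjusted p = 1.15e-16), GNG11 (4.22) and the embryonic globin gene HBE1 (2.10, SE 0.12, from 1461 to 6250 CPM, adjusted p = 1.69e-15) rose. CDCA7L lies on chromosome 7 from 21900899 to 21945903 and HBE1 on chromosome 11 from 5268345 to 5505652. PAGE5 was at least 620-fold lower, with 0 counts in J2_7 cells. MUC15, RCN1, MARCHF1, TOX, UBASH3A, ANK3 and the cytokine receptor gene CSF2RB were also at 0 counts in J2_7 cells, at least 58.5 to 91.7-fold lower. Erythroid genes were higher in J2_7 cells (14 of 31 and 1 lower, the same adjusted over the list alone; median 0.48, adjusted p = 2.83e-12), with HBZ (1.51) and HBA2 (1.47). Myeloid genes were lower (9 of 14 and 1 higher, the same adjusted over the list alone; median -1.46, adjusted p = 2.45e-14), with TYROBP (-4.70), CTSS (-4.05) and SPI1 (-1.54). Integrated stress response genes were lower (12 of 16, 12 adjusted over the list alone; median -0.84, adjusted p = 8.19e-15), as were interferon response genes (9 of 17, 9 adjusted over the list alone; median -0.70, adjusted p = 0.000436). Germline genes had 3 of 5 lower (3 adjusted over the list alone; adjusted p = 0.0407; adjusted p = 0.103 with an estimated correlation). Other variant PRC1 subunit genes had 1 of 10 higher, FBRSL1 (1 adjusted over the list alone; median 0.22, adjusted p = 0.0354; adjusted p = 0.155 with an estimated correlation). Integrated stress response genes rose with ligand in mAID cells (4 of 16, 4 adjusted over the list alone; median 0.20, adjusted p = 1.61e-10) and fell with GSK343 (3, 3 adjusted over the list alone; median -0.35, adjusted p = 2.9e-16), where CHAC1 (-0.996) and DDIT4 (-0.94, SE 0.09, adjusted p = 7.77e-08) fell.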

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

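The tests of the exon count and of pseudogenes without a partner, both tests of BCOR RNA, and the test of DDX46 in LF against EV cells were chosen only after the results were seen. Differences between groups were picked out where the difference itself passed a test, or where a named gene moved one way in every library of one table and the opposite way in every library of another.

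Genes that resemble copies of other genes rose with GSK343 in the inhibitor table, where processed pseudogenes took 0.213 to 0.236% of counts in the 6 libraries with GSK343 and 0.122 to 0.13% in the 6 without. Among processed pseudogenes, those with an expressed partner of similar sequence had a median log2 fold change of 1.33 (370 genes) and those without a partner 0.016 (89 genes, 95% interval -0.07 to 0.10), which argues against a rise of the whole class. A part of these 89 did rise, with 13 called higher and 1 lower. Of 11112 protein-coding genes without a partner, 327 were called higher and 30 lower. Reads shared with a partner could not be told apart from a change of the genes themselves by the difference between protein-coding genes with and without a partner (0.13, interval -0.02 to 0.30, 60 genes), nor by the rank correlation of the gain with the partner's CPM (0.289, interval 0.192 to 0.38). Reads from spliced partners, which would land on genes with 1 exon, could not be told apart either (difference from genes with several exons 0.68, interval -0.26 to 1.97, 16 genes). In the J2_7 table the 78 processed pseudogenes tested had medians of -0.04 in mAID and 0.01 in J2_7 cells with GSK343. That table holds estimated counts per symbol, while the inhibitor table holds counts per gene ID with 459 processed pseudogenes tested. The tables are therefore not alike, and the lack of a rise in the J2_7 table does not decide the cause.

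BCOR RNA rose with the ligand in BCOR-degron cells, KDM2B-degron cells, EV, dLRRS and inhibitor-table cells. In mAID and J2_7 cells it stood at 0.544 (SE 0.115) and 0.573 (SE 0.116) with ligand, under the fold threshold. A part of the degron cassette in the BCOR gene stays open in BCOR-degron cells, where the rise at 72 h was larger (1.81, SE 0.08) than in KDM2B-degron cells (0.82, SE 0.06), a value that belongs to the pattern itself. An effect of the ligand that does not pass through KDM2B is argued against by the difference of SF from EV cells (-0.66, SE 0.07, adjusted p = 2.67e-07). For the other cells, release of BCOR from repression by PRC1.1 is a hypothesis that is consistent with this difference, and with the higher BCOR RNA of dCxxC than EV cells with DMSO (1.27, SE 0.05). The other construct lines, which also had more KDM2B RNA than EV, did not show a rise of BCOR with DMSO. Against EV it stood at -0.45 (SE 0.05) in dLRRS, 0.064 in LF and 0.053 in SF cells. The hypothesis was found and tested on the same data, and neither chromatin nor the stability of the RNA was read here.

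DDX46 rose with the ligand in LF and SF cells. Loss of KDM2B as the cause is argued against by the difference of LF from EV cells (0.047, SE 0.08), and reads from a neighbouring gene by the largest gain among 5 genes within 20 kb (TXNDC15), 1.6% of the gain of DDX46 in CPM of unscaled totals. The rise was called in EV cells too (0.64), at 24 and 72 h of BCOR loss (0.79 and 0.74), in the inhibitor table (0.73) and in mAID cells (0.71), and stood at 0.38 and 0.43 in dLRRS and dCxxC cells under the fold threshold. It was not called at 24 and 72 h of KDM2B loss (0.39 and 0.55) or with ligand in J2_7 cells (0.50). At 2 and 8 h DDX46 stood at -0.011 and 0.149 with BCOR loss and 0.107 and 0.232 with KDM2B loss, not called. An effect of the ligand on this gene without a degraded subunit, with or without a part for the constructs, stays open, since no group of untagged cells was used here.

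The effect of the ligand differed from that of EV in 119 genes for LF, among them CYP2F2P (1.80), AKR1C2 (0.83), CAPN6 (0.78), AIF1L (-1.87), VWA1 (-1.66) and EMILIN2 (-1.57). For SF cells 116 genes differed, with CYP2F2P (1.49), NT5DC4 (1.15), AKR1C2 (1.097), SLC12A7 (-1.99), TSPAN9 (-1.91) and AIF1L (-1.75). For dLRRS cells 6 genes differed, with PCDH1 (1.41), EEF1A2 (1.23) and EGR1 (0.68). For dCxxC cells 241 genes differed, with AKR1C2 (1.04), CA1 (0.94), AKR1C1 (0.82), FGFR1 (-2.97), GATA6 (-2.92) and NXPH4 (-2.65). With 1 library left out the counts ran from 77 to 113 for SF and from 1 to 71 for dLRRS cells, where 71 came without EV ligand library 2 and 77 without EV DMSO library 1. Some alternative ended the calls of AKR1C2, CAPN6 and VWA1 for LF, NT5DC4, SLC12A7 and TSPAN9 for SF, PCDH1 and EGR1 for dLRRS and FGFR1 for dCxxC cells.

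The effect of the ligand differed between J2_7 and mAID cells in 1 gene, LSR (0.77), and that of GSK343 in 18, with ELOVL7 (1.51), CD69 (1.11) and DDIT4 (1.02). The effect of both treatments differed in 64 genes, with GPRC5C and its repeated entry GPRC5C_1 (4.48 each), FERMT2 (3.76), TUBB2B (-1.97), TUBA1A (-1.09) and PRNP (-0.93). With 1 library left out these counts ran from 0 to 1, 8 to 20 and 24 to 214, where 214 came without mAID library 3 and 24 without J2_7 DMSO library 3. The call of PRNP ended in 14 alternatives, FERMT2 in 12, TUBA1A in 9 and GPRC5C in 7, and those of LSR, ELOVL7 and CD69 in 2 to 9. GPRC5C had 0 counts in J2_7 cells with DMSO and 36 with both treatments (at least 13-fold), and FERMT2 had 1 count against 38 (41.3-fold, counting interval 6.98 to 1670), so the fitted differences of these genes are no bounds. HSPA1A moved by 0.48 at 24 h of BCOR loss and by -1.78 at 24 h of KDM2B loss, and the difference was not tested. With GSK343 in the inhibitor table and in mAID cells, CHAC1 moved by 1.12 and -0.996, DDIT4 by 0.81 and -0.94 and SLC7A11 by 0.53 and -0.59, and with both treatments CHAC1 moved by 0.82 and -0.99, and these differences were not tested.

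Each pair of groups allows 10 splits of its libraries, too few for a test, and the real split called the most genes or shared the most with another. Real against highest other counts were 118 and 3, 382 and 8, 592 and 0, and 1004 and 0 for BCOR loss at 2, 8, 24 and 72 h, and 255 and 16, 616 and 0, 1817 and 0, and 1526 and 0 for KDM2B loss. With ligand they were 520 and 13 in EV, 1 and 1 in LF (2 splits as large), 3 and 2 in SF, 542 and 0 in dLRRS and 3 and 0 in dCxxC cells. Between lines with DMSO they were 2427 and 1 (LF), 2171 and 2 (SF), 1901 and 0 (dLRRS), 3060 and 0 (dCxxC) and 2087 and 0 (J2_7). In the inhibitor table they were 341 and 0, 613 and 0, and 1427 and 0, in mAID cells 338 and 0, 97 and 0, and 923 and 1, and in J2_7 cells 350 and 0, 339 and 9, and 966 and 0, for ligand, GSK343 and both.

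Of 60 splits per interaction, as many or more genes as in the real one were called in 6 for LF (119 real, 351 highest other), 6 for SF (116, 240), 5 for dLRRS (6, 379) and 6 for dCxxC cells (241, 384). For J2_7 against mAID cells it was 8 with ligand (1, 283), 6 with GSK343 (18, 589) and 4 with both (64, 1180). Splits that swap or mix the treatments within one line call the treatment effect itself, which follows from how the splits are made. Chance was therefore neither tested nor excluded by these splits. The interaction in the inhibitor table called 0 genes, a count that each of its 60 splits reaches (highest other 0), so its splits test nothing.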

How the results depend on the processing

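The alternatives without shallow libraries, without repeated entries and without copies were chosen only after the data were seen. DESeq2's size factors left all 35 counts within 1.5 times, leaving out shallow libraries 15 of 15 and leaving out repeated entries 10 of 10. Of 493 values of named genes 335 were called, 74 of these lost the call in some alternative, all 74 of them when 1 library was left out, and 0 turned around. Calls were lost in 35 with only the groups compared, 20 with DESeq2, 11 without shallow libraries, 6 without a filter, 1 with size factors and 1 without repeated entries. Of the list results 111 lost the call with an estimated correlation and 676 did not change. Causes of the moves below were not tested except where the number of samples or genes is named.

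With only the groups of the comparison, where fewer libraries set the dispersion, counts fell to 63 and 225 at 2 and 8 h of BCOR loss. For the difference of the ligand effect from that of EV they fell to 45 for LF, 76 for SF and 2 for dLRRS. With GSK343 they fell to 365 in the inhibitor table, 44 in mAID and 197 in J2_7 cells. The differences of GSK343 and of both between J2_7 and mAID cells fell to 10 and 39. Without a filter on low counts, where more genes are tested, counts were 27 with ligand in LF, 6 in SF and 7 in dCxxC cells. They were 4 for the interaction in the inhibitor table and 184 for GSK343 in mAID cells (112 higher, 72 lower). For the differences of ligand, GSK343 and both between J2_7 and mAID cells they were 15, 81 and 175. For the difference of the ligand effect from that of EV, 41 were called for dLRRS, and 33 higher and 77 lower for LF. DESeq2 called 3 with ligand in LF cells and 54 with GSK343 in mAID cells, and without copies GSK343 called 360 in the inhibitor table.

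With an estimated correlation the genes that rise with KDM2B loss no longer passed for ligand in SF cells (median 0.079, adjusted p = 0.0628) and LF against EV with DMSO (-0.13, adjusted p = 0.266). The falling genes no longer passed for LF (-0.30, adjusted p = 0.157) and dLRRS against EV with DMSO (0.029, adjusted p = 0.299), for both treatments in the inhibitor table (-0.023, adjusted p = 0.0924), in mAID (-0.071, adjusted p = 0.237) and in J2_7 cells (-0.10, adjusted p = 0.0887), and for J2_7 against mAID with DMSO (-0.066, adjusted p = 0.23). With size factors the rising genes had -0.11 in LF against EV with DMSO (adjusted p = 0.0642). With the list taken at 24 h, medians of the falling genes were -0.057 with ligand in LF cells, -0.024 in SF cells, 0.035 for LF minus EV, -0.13 for SF against EV with DMSO, -0.077 with GSK343 and 0.045 for the interaction in the inhibitor table, 0.25 for J2_7 against mAID with DMSO, which turned around (adjusted p = 1.1e-06), and the rising genes had 0.051 for both treatments in J2_7 minus mAID cells.

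With single libraries left out, counts ranged from 74 to 126 at 2 h and 391 to 671 at 24 h of BCOR loss. They ranged from 403 to 649 at 8 h of KDM2B loss, 1 to 25 with ligand in LF and 0 to 3 in dCxxC cells. For the difference of the ligand effect from that of EV they ranged from 77 to 113 for SF and 1 to 71 for dLRRS. Ranges were 211 to 276 with ligand in the inhibitor table, 55 to 98 with GSK343 in mAID and 231 to 303 with ligand in J2_7 cells. The differences of ligand, GSK343 and both between J2_7 and mAID cells ranged from 0 to 1, 8 to 20 and 24 to 214. In all, 41 such counts moved by more than 1.5 times and 217 did not, where fewer libraries are a part of each move. The count of 71 came without EV ligand library 2, that of 25 without LF ligand library 1 and that of 214 without mAID library 3 with both treatments.

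Replicate numbers were not taken to pair the libraries, since not every correlation of residuals between libraries of the same number was over 0.1. In the BCOR table these correlations ran from -0.07 to 0.281 (median 0.09, 14 of 30 over 0.1, against -0.044 and 2 of 60 for other numbers) and 14 of 15 libraries correlated best with their own number, a hint of pairing from the data and not from the design. In the J2_7 table they ran from -0.245 to 0.149 and 1 of 24 libraries did. With the block each of the 14 counts stayed within 1.5 times, and of 216 values of named genes 6, all in the J2_7 table, lost the call. Depth limits the 7 shallow libraries, the smallest being J2_7 GSK343 library 1 with 782663 counts.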

Other observations

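The 380 genes higher at 72 h after both BCOR and KDM2B loss (40 if independent) come from tables that have no library in common. Both tables set cells with the same ligand against untreated cells, without a vehicle or untagged group. Effects common to the treatment are therefore part of this overlap. Within a table, part of the excess of shared genes may come from the 3 control libraries that both comparisons use. The simulations with shared controls gave a covariance of 0.0277 against 0.153 for 24 and 72 h of BCOR loss, and without shallow libraries the counts stayed within 1.5 times (15 of 15).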
